A study of Homo sapiens with 16 samples.

How the data were processed

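RNA-seq was done on MDA-MB-231 cells, a human breast cancer line, as wild type (WT) and as BMAL1 knockout (KO), each under control, cisplatin, doxorubicin and tunicamycin. There were 16 samples in 8 groups of 2, which the labels call biological replicates. Doses and times are not given in the sources used here. Per the labels' protocols, total RNA was treated with DNase, libraries were made with an mRNA kit, and sequencing was paired-end on an Illumina HiSeq. The extraction protocol speaks of fibroblast lines, while the other labels name MDA-MB-231 cells. Groups were taken from the labels for genotype and treatment. Per the submitters' processing notes, FastQC 0.11.5, Trimmomatic 0.35, STAR 2.5.3, Cufflinks, Cuffdiff (versions not given in the sources used here) and build hg38 were used. Their roles and order, the annotation release and the use of strand in counting are not given in the sources used here, so overlapping and antisense genes are uncertain.

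The authors deposited 4 tables, 1 per treatment, each comparing WT with KO cells over 60658 Ensembl genes. Per the file headers, each table holds 1 FPKM value per group, made by the authors with Cuffdiff from both replicates. The log2 values deposited by the authors are the ratio of the KO over the WT FPKM with no pseudocount, which recomputation from the FPKM matched to within 4.64e-05. The score deposited by the authors is the test statistic of Cuffdiff per gene. The p-values deposited by the authors are multiples of 5.0e-05, and each q-value is the p-value after Benjamini-Hochberg adjustment over the tested genes of its table, which recomputation matched to within 5.25e-07. The columns were assigned to WT and KO from the order of groups in the file names and from the group codes inside the tables. No value per library was given, so standard deviations, refits and tests across replicates could not be computed. The p-values are the authors' and measure the spread that Cuffdiff estimated. The tables were normalized separately, and tests stay within a table. Counts per library are not given, and the relative depth of a group was read from the steps of values up to 0.150 FPKM, which mix depth with the scaling of each table. At most 17.5% of the genes used lay within 0.05 log2 of the step taken, so it is a rough guide. On simulated data a depth ratio of 1.8 was found as 1.80, but 2.3 was found as 1.15, so large ratios can be read too low. As a second measure, the 5th percentile of values above 0 in WT control over that of the group was 1.35 for KO control, 2.05 and 1.62 for WT and KO in cisplatin, 2.74 and 2.22 in doxorubicin, and 1.84 and 1.76 in tunicamycin. A deeper group has smaller error, but no interval can be given without counts.

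Before the data were examined, the tests, the gene lists, the rule for named genes and the alternatives were fixed, apart from a z with the deposited statistic and the removal of genes in shifted windows, which were added later, as were the tests that the closing section names as chosen after the results were seen. A gene was called where the authors tested it and its q was at most 0.05. Of the calls, 66, 40, 37 and 39 in control, cisplatin, doxorubicin and tunicamycin had 1 group listed at 0 and no finite ratio, and they entered counts only. The difference of the log2 ratio between a drug and control was to be tested by a z only if the deposited p-values followed the normal tail of the deposited statistic. They did not, since the normal quantile of p was a median of 1.50, 1.48, 1.52 and 1.50 times the statistic in the 4 tables. The difference is therefore given as a value, in genes of FPKM 5 or more in 1 group of each table. The response to a drug within a genotype was the log2 ratio of FPKM with a pseudocount of 1 across tables, with no test. That scale understates the change of low genes. Overlaps were set beside those of independent lists (product of both counts over the genes tested in both tables). For 29 gene lists, calls were counted over all tested genes and after Benjamini-Hochberg adjustment of the deposited p-values over the list alone. Calls in a list were set against those of other tested genes by Fisher's exact test (2-sided, adjusted over 116 tests). The list's median log2 ratio was given its percentile among 10000 random lists of the same size, matched on mean FPKM in 20 bins, as a description of these libraries. The lists were clock positive arm, clock E-box targets, apoptosis effectors, apoptosis inhibitors, p53 targets, nucleotide excision and crosslink repair, double-strand break repair, G2/M proliferation, S-phase replication, unfolded protein response, PERK-ATF4 stress, oxidative stress (NRF2), metallothionein and drug transport, mesenchymal and invasion, epithelial, collagens and matrix, inflammatory cytokines, interferon response, antigen presentation, hypoxia and angiogenesis, glycolysis, cholesterol and lipid synthesis, immediate early genes, and Wnt, Notch and TGF-beta signalling. Mitochondrial genome and histone genes served as signs of RNA quality, and fibroblast, luminal breast and leukocyte markers as signs of other cell types.

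Named genes were the clock genes, the 10 highest and 10 lowest log2 ratios among calls with an FPKM of at least 5 in the higher group and above 0 in the lower one, and up to 4 called members per list with the largest ratios. To these came the 10 genes per direction called in all 4 tables with the largest smallest ratio, and the 5 highest and 5 lowest differences per drug. Merged loci, small RNAs and genes that tell the sex of a donor were left out. Some genes that the rule takes are not reported here. Positions and gene types came from GENCODE 29 (GRCh38), in which 57047 of 60658 gene IDs and 15155 tested ones were found. Of the latter 98.0% lay in the deposited locus within 1000 bases. The search for shifted chromosome windows used windows of 10 Mb with at least 15 genes tested in all tables and 1000 shuffles of gene positions (seed 1). A window was taken as shifted where its median log2 ratio was at least 0.3 in size with the same sign in all 4 tables. Families of near-identical genes, such as SPANX, POTE, HLA, AKR1C, metallothionein and IFITM genes and pseudogenes, are uncertain because fragments can be split among copies. The calls, the z of a difference, the list percentile, the window search and the depth steps were tested on simulated data, and the other steps were not. With deposited values of KO against WT control as the base (12803 genes), 22 of 67 genes changed by 0.5 log2 were recovered, 54 of 67 changed by 1 and 62 of 66 changed by 2, with 10 false calls. For the same comparison 194 of 200 shifted lists were found, and 9 of 200 lists with no shift lay outside the middle 95%. The z of a difference recovered 37 of 67 in cisplatin, 33 of 67 in doxorubicin and 41 of 67 in tunicamycin at 1 log2. For the calls and this z, simulated noise was normal, with the standard error taken from the deposited statistic. The deposited p-values do not follow that tail, so the simulation does not give the sensitivity or error of the authors' calls. The window search found 5 of 5 simulated windows shifted by 0.8 log2 and 0 others, and smaller shifts were not simulated. Alternatives tried were a q of 0.01, a minimum log2 ratio of 1, a minimum FPKM of 1, recomputed adjustment, single symbols, centring, pseudocounts of 1 and 0.1, z tests of the differences, and removal of genes in shifted windows. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.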

Results

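Gene expression was measured by RNA-seq in MDA-MB-231 cells, an established line of triple-negative human breast cancer, and in the same line with BMAL1 (gene symbol ARNTL) knocked out. BMAL1 is the transcription factor that drives the circadian clock together with CLOCK. Each genotype was left untreated or given cisplatin, which crosslinks DNA, doxorubicin, which intercalates into DNA and poisons topoisomerase, or tunicamycin, which blocks N-linked glycosylation and stresses the endoplasmic reticulum. The 16 samples fall into 8 groups of 2 biological replicates. Per the labels, cisplatin and doxorubicin stand for drugs that start apoptosis, and tunicamycin is a comparison treatment in which little dependence on BMAL1 was foreseen. The question is how loss of BMAL1 changes expression without drug and under each drug. The authors deposited 1 table per treatment, with 1 FPKM value per group (fragments per kilobase of transcript, scaled to the sequenced total), so no spread between replicates can be given here. Their test per gene compared KO with WT cells within a table, and a gene is said to be called where their q was at most 0.05. Levels are the authors' group FPKM and are written from WT to KO. The tables were normalized separately, so levels are tested only within a table. Of 60658 genes per table, 12978 were tested in control, 14253 in cisplatin, 11856 in doxorubicin and 13896 in tunicamycin. Counts per library are not given in the sources used here, and depth is read only in relative terms, with the scaling of each table included, from the steps of low values. By these steps the untreated WT group was the shallowest, with KO control at 1.4 times its depth, cisplatin at 2.27 (WT) and 1.83 (KO), doxorubicin at 2.05 and 1.66, and tunicamycin at 1.88 and 1.89.

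ARNTL itself had a smaller FPKM in KO than in WT cells in every table, at 5.67 to 0.889 in control, 1.26 to 0.941 in cisplatin, 1.31 to 0.474 in doxorubicin and 3.25 to 2.24 in tunicamycin. The gene lies on chromosome 11, 13276652 to 13387266 (GRCh38, plus strand, the whole gene). In the authors' deposited table its log2 ratio was -2.67 (q = 0.000213) in control and -1.47 (q = 0.00509) in doxorubicin. The control q is the smallest in its table, shared by 3044 of 12978 tested genes, so it does not rank ARNTL among them. The ratio was -0.42 (q = 0.467) in cisplatin and -0.53 (q = 0.0810) in tunicamycin in the authors' deposited table, which did not pass the threshold. The edited part of the gene is not stated in the labels, and a group FPKM covers all exons, so transcripts that carry a small edit would still be counted.  NR1D2 (REV-ERB beta), a repressor in the second loop of the clock, was called lower in all 4 tables, at 20.1 to 1.91 in control, 18.1 to 3.0 in cisplatin, 6.57 to 0.676 in doxorubicin and 19.7 to 3.84 in tunicamycin. PER2, a core repressor of the clock, and TEF, an output transcription factor of the PAR bZIP family, were higher in KO cells in control, cisplatin and tunicamycin. PER2 went from 0.588 to 2.79 in control, 1.56 to 4.45 in cisplatin and 0.917 to 4.71 in tunicamycin. In the same tables TEF went from 1.15 to 3.29, 1.76 to 3.73 and 1.46 to 4.49. NPAS2, a paralog of CLOCK, was called higher in control (20.7 to 59.5), doxorubicin (22.3 to 33.1) and tunicamycin (42.8 to 59.0) but was 14.4 to 13.9 in cisplatin. It lies in a chromosome segment whose genes were shifted upward. RORA, an activator of ARNTL, was lower in control (1.14 to 0.204) and cisplatin (1.23 to 0.123). CIART, a further clock repressor, was lower in cisplatin (1.98 to 0.505). CRY1 was called higher in control (15.9 to 25.3) and tunicamycin (18.2 to 30.6), although the segment it lies in was shifted downward. PER1 was higher in cisplatin (8.67 to 12.7) and tunicamycin (5.40 to 10.3). BHLHE40 was lower in cisplatin (14.8 to 8.93), and BHLHE41 was higher in control (0.848 to 3.65) and tunicamycin (0.913 to 1.85). CLOCK itself was lower in cisplatin (5.02 to 3.27). Among E-box targets of the clock, higher and lower calls numbered 4 and 1 of 11 in control, 5 and 3 of 13 in cisplatin, 0 and 2 of 7 in doxorubicin and 6 and 1 of 12 in tunicamycin (adjusted over the list alone, 5 and 1 in control). The median log2 ratio of this list was 0.53 in control, 0.47 in cisplatin, 0.04 in doxorubicin and 0.75 in tunicamycin, and it lay outside the middle 95% of matched random lists in control, cisplatin and tunicamycin. The positive arm list includes ARNTL itself and NFIL3, which were among its lower calls in control. Its higher and lower calls numbered 1 and 3 of 6 in control, 1 and 2 of 6 in cisplatin, 1 and 2 of 6 in doxorubicin and 2 and 1 of 6 in tunicamycin (adjusted over the list alone, 2 and 3 in control). Its medians were -0.13 in control, -0.24 in cisplatin, -0.57 in doxorubicin and -0.03 in tunicamycin. Neither clock list passed Fisher's exact test of calls against other genes in any table. Without the genes of shifted chromosome segments the control median of E-box targets lay inside the middle 95% (percentile 94.6). Without them 4 tested members of the positive arm were left, ARNTL itself among them. Their median lay below the middle 95% in control (-1.15) and doxorubicin (-0.94).

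**Figure D1:**
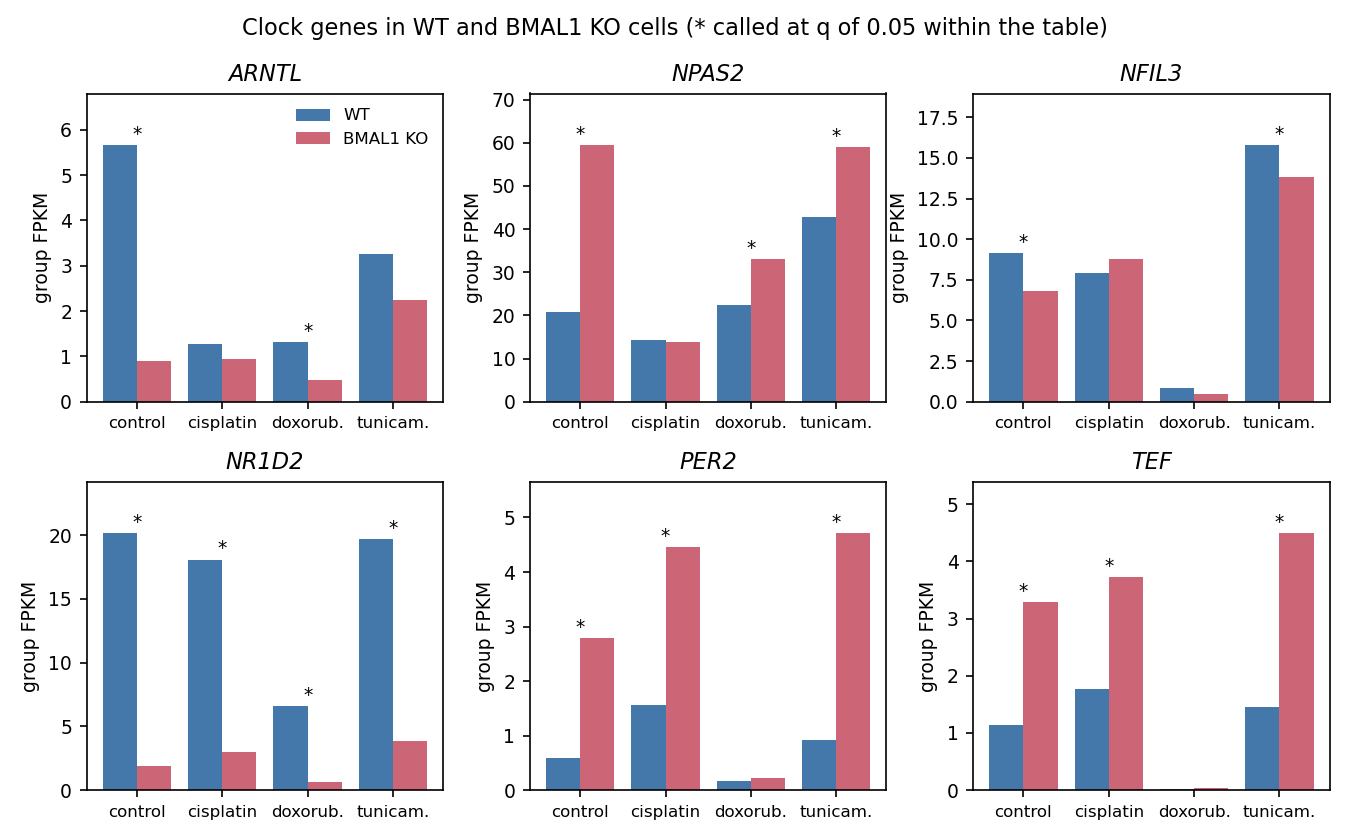
Bars give the authors' group FPKM (vertical axis, from 0) of 6 clock genes in WT and BMAL1 KO cells under each treatment (horizontal axis), with a star where the gene was called at q of 0.05 within that table. NR1D2 was lower in KO cells in all 4 tables (20.1 to 1.91 in control), while PER2 and TEF were higher in KO cells in control, cisplatin and tunicamycin.

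Many of the differences between KO and WT cells recurred under every treatment. Of 10881 genes tested in all 4 tables, 979 were called higher in KO cells in each and 942 lower in each. Independent lists of the same sizes would share 62.8 and 35.3. The tables have no libraries in common, so no shared control adds to these overlaps. The cancer-testis antigen SPANXB1 (chromosome X, 141002591 to 141003706, GRCh38) was higher in KO cells at 6.91 to 837 in control, 8.48 to 1089.8 in cisplatin, 13.8 to 1637 in doxorubicin and 4.79 to 731 in tunicamycin. SPANX genes are near-identical copies on the X chromosome, so the split of fragments among them is uncertain. KYNU, the kynureninase of tryptophan breakdown (chromosome 2, 142877498 to 143055832), went from 0.527 to 37.9 in control, 0.362 to 20.7 in cisplatin, 0.407 to 31.2 in doxorubicin and 0.552 to 49.3 in tunicamycin. Higher in all 4 tables too were the secreted protein OLFML3 (0.245 to 17.6 in control), FERMT3 (kindlin-3, an integrin activator of blood cells, 1.91 to 64.5), the adhesion molecule CADM4 (1.92 to 53.3) and the cytokine subunit EBI3 (0.333 to 12). So were the cytokine IL1B (1.02 to 12.4), the hexosamine pathway enzyme GFPT2 (3.46 to 73.4), LCP1 (L-plastin, an actin bundler of leukocytes, 1.94 to 28.6) and the long noncoding RNA MIR3681HG (0.784 to 69.9). Lower in all 4 tables was MMP1, the interstitial collagenase (chromosome 11, 102789920 to 102798160), at 93.1 to 2.62 in control, 83.2 to 2.76 in cisplatin, 126 to 4.68 in doxorubicin and 80.3 to 4.21 in tunicamycin. EFEMP1 (fibulin-3, chromosome 2, 55865967 to 55924139) went from 51.2 to 1.24 in control, 34.1 to 0.883 in cisplatin, 49.6 to 1.68 in doxorubicin and 42.6 to 1.38 in tunicamycin. The long noncoding RNA UCA1 went from 80.6 to 2.02 in control, 75.4 to 3.61 in cisplatin, 105 to 2.45 in doxorubicin and 62.7 to 2.16 in tunicamycin. The other genes of this group were CLEC11A, a secreted growth factor (16.4 to 0.351 in control), SPNS2, an exporter of sphingosine-1-phosphate (10.4 to 0.676) and the cytokine IL24 (13.6 to 0.520). To them belonged NOV (CCN3, 10.7 to 0.493), LINC00707 (14.0 to 0.525), the zinc finger gene ZSCAN18 (7.14 to 0.626) and stomatin, STOM (23.7 to 0.791), which lies in a segment shifted downward. Control shared 1631 (805) higher calls with cisplatin, 1524 (684) with doxorubicin and 1974 (848) with tunicamycin, where the number in parentheses is that of independent lists. The lower calls shared were 1568 (707), 1359 (538) and 1685 (631). Across genes, which are not independent replicates, Pearson's r of the log2 ratios with control was 0.662 for cisplatin, 0.737 for doxorubicin and 0.764 for tunicamycin (Spearman's rho 0.491, 0.604 and 0.641). Called in opposite directions were 746 genes between control and cisplatin, 453 between control and doxorubicin and 420 between control and tunicamycin. The labels name no clones, so a difference between KO and WT cells cannot be told from one between cultures or clones.

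Part of the recurring differences followed chromosome position. In 27 of 254 windows of 10 Mb (GRCh38), the median log2 ratio was at least 0.3 in size with the same sign in all 4 tables. After random shuffling of gene positions, at most 1 window reached this in any of 1000 shuffles. On chromosome 13, 7 windows between 30000001 and 120000000 were higher in KO cells, with median log2 ratios over their 152 genes of 0.79 in control, 1.12 in cisplatin, 0.89 in doxorubicin and 1.05 in tunicamycin. Lower in KO cells were 2 windows of chromosome 7 between 1 and 30000000, with medians of -1.07, -1.22, -0.98 and -1.16 over 88 genes. Windows on chromosomes 6, 8, 9, 11 and 12 were also lower, with control medians of -0.59, -0.51, -0.44, -0.55 and -0.53, and 1 window of chromosome 2 was higher (0.37). Some windows missed the bound narrowly, such as 120000001 to 130000000 on chromosome 12 (-0.34, -0.297, -0.38 and -0.297). Their genes count as outside, and they stay in where genes of shifted windows are removed. The 27 windows held 354 of 1911 recurring calls with a position, or 18.5%, and 8.28% of the genes tested in all tables. They are called shifted segments here. Among the named genes inside them were LCP1, COL4A1, COL4A2, DNAJC3, ERCC5, LIG4, BRCA2, RFC3 and LINC00452 on chromosome 13, NPAS2 on chromosome 2, CA8 on chromosome 8, CD44 and DDB2 on chromosome 11, XPA, STOM, PSAT1 and BAG1 on chromosome 9, and APAF1, TXNRD1, CRY1, MVK, OAS2 and RFC5 on chromosome 12. The change of such a gene can be far larger than that of its window, as for STOM in control (-4.90 beside -0.41).

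**Figure D2:**
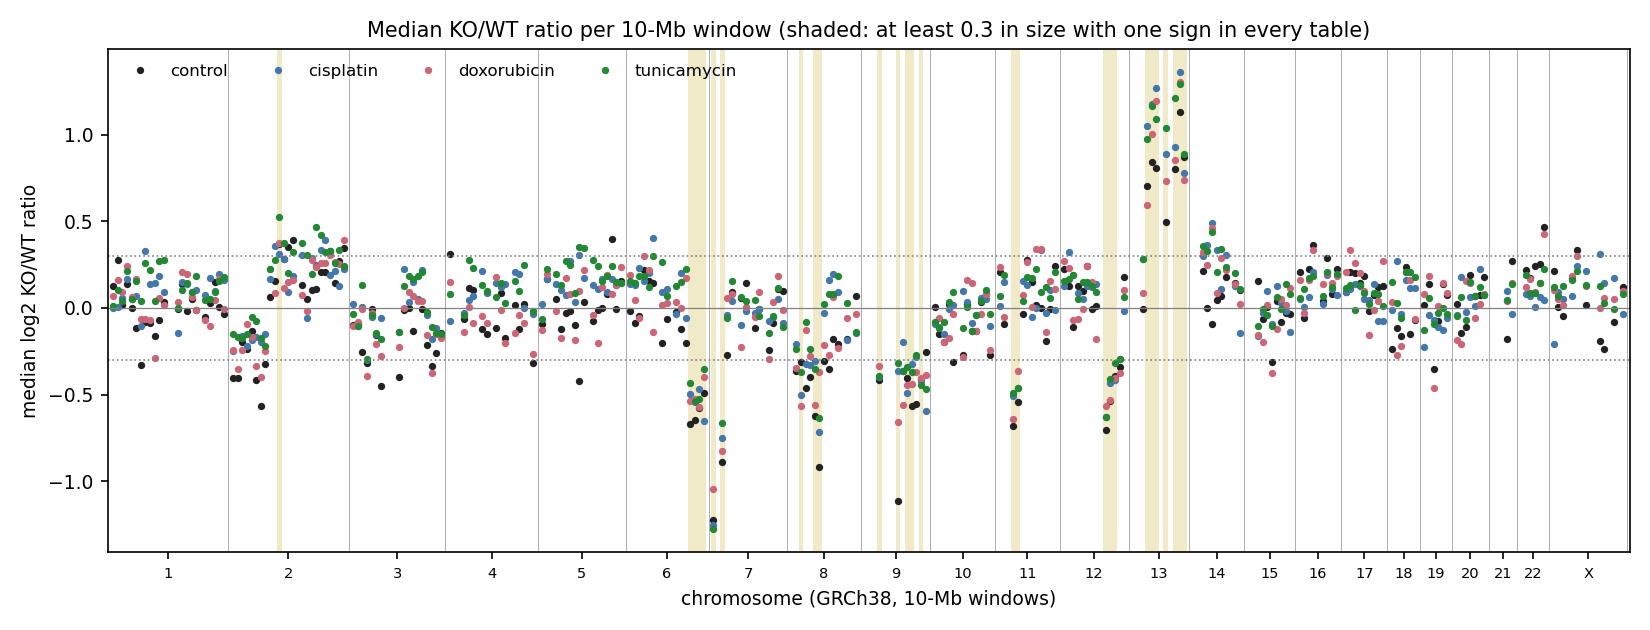
Points give the median log2 KO/WT ratio (vertical axis) of each 10-Mb window with at least 15 genes, along the chromosomes in GRCh38 (horizontal axis), in each of the 4 tables. Dotted lines mark 0.3 and -0.3, and shading marks the 27 windows beyond them with the same sign in all tables, among them 7 higher windows on chromosome 13.

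Without drug, 5688 of 12978 tested genes (43.8%) were called, 2948 higher and 2740 lower in KO cells. Among the most raised genes were the cytokine gene CSF3 (G-CSF) at 0.180 to 15.7 and WNT5A, a ligand of noncanonical Wnt signalling, at 0.139 to 10.5. ACTG2, a smooth muscle actin, was 0.137 to 9.76. Among the most lowered were FGF13, a fibroblast growth factor homolog (14.8 to 0.262), the ligand-gated channel ZACN (7.42 to 0.140), the RNA-binding protein RBPMS (15.1 to 0.513) and the guidance receptor NEO1 (7.11 to 0.264). The iron storage protein FTL, a target of the oxidative stress factor NRF2, went from 2069 to 8634. G2/M genes were lower, including CENPF (148 to 63.4) and CKS2 (448 to 199). Of these calls, 4171 were under 2-fold, 783 at least 2-fold higher and 734 at least 2-fold lower. The mRNAs of the mitochondrial genome, read here as a sign of RNA quality, made up 4.95% of summed FPKM in WT and 3.62% in KO cells.

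Under cisplatin, 7070 of 14253 tested genes (49.6%) were called, 3624 higher and 3446 lower in KO cells. IGFN1, a gene of the immunoglobulin superfamily (0.0751 to 18), the SPANX copies SPANXC (0.748 to 56.1) and SPANXA2 (0.792 to 41.3), CSF3 (0.0962 to 12.2) and WNT5A (0.332 to 9.09) were among the most raised. Among the most lowered were IL24 (25.8 to 0.765), the transcription factor NFATC2 (5.03 to 0.371) and LINC00452 (8.10 to 0.387), the last in a segment of chromosome 13 whose other genes were shifted upward. Genes of Wnt, Notch and TGF-beta signalling were mostly lower, among them INHBA (1.14 to 0.104), WNT7B (13.8 to 3.34) and NOTCH1 (8.60 to 3.23). NOTCH1 lies in a window of chromosome 9 with a median log2 ratio of -0.60 in cisplatin. That window was not taken as shifted because its control median was -0.25. Of the genes for cyclin E, CCNE1 went from 20.8 to 42.8 and CCNE2 from 33.8 to 55.6. At least 2-fold higher were 570 calls and at least 2-fold lower 898, so that 38.8% of calls of this size were higher, against 51.3% of all calls. Mitochondrial mRNAs made up 4.57% of summed FPKM in WT and 3.16% in KO cells.

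Under doxorubicin, 5348 of 11856 tested genes (45.1%) were called, 2890 higher and 2458 lower in KO cells. The sorting receptor SORCS2 (0.0652 to 9.91), the calcium channel subunit CACNA2D4 (0.157 to 21.8), FERMT3 (1.0 to 99.8) and PECAM1, an adhesion molecule of endothelial and blood cells (0.154 to 10.3), were among the most raised. The most lowered was CA8, a carbonic anhydrase-related protein (9.31 to 0.0314), which lies in a segment of chromosome 8 shifted downward. NEO1 (10.9 to 0.394) was also lower. In antigen presentation, 17 of 20 tested genes were higher and 0 lower, among them HLA-DRA (4.16 to 14.6) and PSMB10, a subunit of the immunoproteasome (26.0 to 77.2). The glucose transporter SLC2A1 (249.9 to 66.3) and the TGF-beta receptor TGFBR2 (8.61 to 1.55) were lower. At least 2-fold higher were 648 calls and at least 2-fold lower 847. Mitochondrial mRNAs made up 9.71% of summed FPKM in WT and 9.37% in KO cells.

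Under tunicamycin, 6852 of 13896 tested genes (49.3%) were called, 3784 higher and 3068 lower in KO cells. The cadherin CDH18 (0.0459 to 7.68), CACNA2D4 (0.241 to 38.0), CSF3 (0.220 to 28.0), WNT5A (0.203 to 19.7) and the cytokine genes IL1B (0.849 to 68.6) and IL1A (0.335 to 12.5) were among the most raised. Among the most lowered were IL24 (16.0 to 0.220), FGF13 (10.8 to 0.197), NEO1 (9.91 to 0.353), the centrosomal gene CEP97 (79.7 to 3.91) and the surface antigen CD24 (12.3 to 0.608). NRF2 target genes were higher in 18 of 20 tested members and lower in 0, with AKR1C1, an aldo-keto reductase (1.43 to 18.4), and NQO1, a quinone reductase (319 to 1094), as examples. Genes of the unfolded protein response, the pathway that tunicamycin engages, were higher in KO cells in 17 of 24 tested members and lower in 3, and the median log2 ratio of 0.25 lay inside the middle 95% of matched random lists. At least 2-fold higher were 638 calls and at least 2-fold lower 777. Mitochondrial mRNAs made up 6.37% of summed FPKM in WT and 3.60% in KO cells.

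The fixed gene lists describe these differences by function. Lists were compared with other tested genes by Fisher's exact test (2-sided, Benjamini-Hochberg adjusted over 116 tests of 29 lists in 4 tables), and their median log2 ratio with 10000 random lists of matched level. Genes are not independent replicates, so these p-values describe lists of genes in these libraries. Of the 116 tests, 42 passed. Fisher's test was not matched on level, so a frequent call in a list of abundant genes is not separated from their level. List counts are of calls among tested members. Medians of the clock positive arm, apoptosis effectors and inhibitors, unfolded protein response, PERK-ATF4, epithelial, interferon, hypoxia and luminal breast lists lay inside the middle 95% of matched lists in every table. Counts adjusted over the list alone are given where they differ. The median and the mean log2 ratio of a list had opposite signs in 23 of the 116 cases, among them metallothioneins and drug transport in cisplatin (-0.23 and 0.55) and Wnt, Notch and TGF-beta signalling in control (-0.28 and 0.05). G2/M genes were lower in KO cells in most tested members except in doxorubicin. Their lower and higher calls numbered 23 and 1 of 30 in control, 24 and 4 of 30 in cisplatin, 11 and 2 of 30 in doxorubicin and 28 and 0 of 30 in tunicamycin (adjusted over the list alone, 23 and 2 in control and 25 and 4 in cisplatin). Calls were more frequent than among other genes in control, cisplatin and tunicamycin (Fisher's exact test, adjusted p = 0.000755 in control, 2.2e-05 in cisplatin and 2.2e-05 in tunicamycin). The median log2 ratio was -0.46 in control, -0.31 in cisplatin, -0.19 in doxorubicin and -0.32 in tunicamycin. Examples were CENPF, a kinetochore protein, at 148 to 63.4 in control, 9.17 to 3.07 in doxorubicin and 77.8 to 40.1 in tunicamycin. HMMR went from 15.3 to 7.35 in control and 8.27 to 4.91 in cisplatin. S-phase genes of DNA replication moved both ways, with higher and lower calls of 10 and 9 of 32 in control, 14 and 5 of 32 in cisplatin, 10 and 12 of 31 in doxorubicin and 9 and 11 of 32 in tunicamycin (the same counts adjusted over the list alone). CDC6 (43.0 to 78.2), a loader of the replicative helicase, and MCM2 (58.9 to 96.8), a subunit of it, were higher in control, while the sliding clamp PCNA was lower in control (221 to 140.2) and doxorubicin (121 to 59.4). RFC3, on chromosome 13, was higher at 27.0 to 45.4 in control and 19.4 to 47.7 in cisplatin. Calls in this list were more frequent than among other genes in doxorubicin (Fisher's exact test, adjusted p = 0.0203), and its median was below the matched lists in tunicamycin (-0.13).

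Genes of apoptosis and DNA repair, which cisplatin and doxorubicin address, moved both ways. Among apoptosis effectors, higher and lower calls numbered 3 and 9 of 24 in control, 5 and 8 of 24 in cisplatin, 3 and 4 of 18 in doxorubicin and 6 and 5 of 24 in tunicamycin (the same counts adjusted over the list alone). The death receptor FAS, also a p53 target, was lower in all 4 tables at 2.96 to 0.971 in control, 4.01 to 1.74 in cisplatin, 1.07 to 0.405 in doxorubicin and 2.13 to 0.563 in tunicamycin. CASP8, the initiator caspase of death receptors, was higher in cisplatin (11.3 to 22.7) and doxorubicin (0.999 to 2.64), and its substrate BID in doxorubicin (81.0 to 141) and tunicamycin (44.5 to 85.0). BCL2L11 (BIM) was lower in control (3.92 to 1.68) and APAF1, in a segment shifted downward, in cisplatin (4.05 to 2.16). For apoptosis inhibitors the numbers were 2 and 5 of 13 in control, 2 and 6 of 14 in cisplatin, 2 and 3 of 12 in doxorubicin and 4 and 5 of 13 in tunicamycin (the same counts adjusted over the list alone). TNFRSF11B (osteoprotegerin) was higher in each table (0.526 to 3.99 in control), BIRC2 was lower in control (70.3 to 37.5), BIRC3 in doxorubicin (1.48 to 0.276) and BCL2L1 in cisplatin (235 to 162). In the p53 target list, higher and lower calls numbered 2 and 8 of 24 in control, 4 and 9 of 25 in cisplatin, 3 and 7 of 19 in doxorubicin and 3 and 6 of 24 in tunicamycin (adjusted over the list alone, 5 and 10 in cisplatin and 2 and 4 in tunicamycin). Its median log2 ratio was -0.28 in control, -0.04 in cisplatin, -0.54 in doxorubicin and 0.01 in tunicamycin, below the middle 95% in control and doxorubicin. Without the genes of shifted segments the doxorubicin median lay inside that range (percentile 32.7). CDKN1A (p21) was lower in control (22.9 to 14.1), CCNG1 was higher in cisplatin (17.4 to 38.1) and tunicamycin (20.2 to 45.3), and GADD45A was lower in doxorubicin (6.75 to 3.32). Nucleotide excision and crosslink repair gave 7 and 7 of 27 in control, 8 and 6 of 27 in cisplatin, 4 and 7 of 20 in doxorubicin and 6 and 8 of 27 in tunicamycin (adjusted over the list alone, 4 and 8 in doxorubicin). ERCC5 was higher (9.91 to 19.7 in control, 10.3 to 28.7 in cisplatin) and XPA lower (16.3 to 7.52), both in shifted segments. FANCD2 was lower in control (25.4 to 13.7) and cisplatin (13.9 to 7.60). Of the 27 members tested in control, 5 lay in shifted segments. Its median was below the matched lists in doxorubicin (-0.36). Double-strand break repair gave 6 and 8 of 32 in control, 14 and 1 of 32 in cisplatin, 7 and 2 of 27 in doxorubicin and 10 and 4 of 32 in tunicamycin (adjusted over the list alone, 6 and 2 in doxorubicin). Its median in cisplatin was 0.22, above the matched lists, but without genes of shifted segments it lay at percentile 96.1. Examples were LIG4 (4.96 to 12.3), XRCC2 (3.88 to 7.26), BRCA2 (3.74 to 6.51) and PALB2 (6.76 to 10.4) in cisplatin, of which LIG4 and BRCA2 lie in shifted segments. None of these 5 lists passed Fisher's exact test of calls against other genes.

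Stress-response genes were mostly higher in KO cells where NRF2 targets were concerned. Their higher and lower calls numbered 14 and 1 of 20 in control, 16 and 2 of 20 in cisplatin, 11 and 3 of 21 in doxorubicin and 18 and 0 of 20 in tunicamycin (adjusted over the list alone, 15 and 1 in control and 12 and 3 in doxorubicin). Median log2 ratios were 0.85 in control, 0.48 in cisplatin, 0.72 in doxorubicin and 1.31 in tunicamycin, all above the middle 95% of matched lists. Calls were more frequent than among other genes in control, cisplatin and tunicamycin (Fisher's exact test, adjusted p = 0.0205 in control, 0.00153 in cisplatin and 0.00153 in tunicamycin). FTL went from 2069 to 8634 in control, 3792 to 12656 in cisplatin, 4453 to 21375 in doxorubicin and 2329.8 to 9059 in tunicamycin, and AKR1C1 from 1.60 to 10.7 in control, 2.26 to 13.0 in cisplatin, 2.06 to 13.1 in doxorubicin and 1.43 to 18.4 in tunicamycin. NQO1 was 413 to 1003 in cisplatin and 439 to 1671 in doxorubicin. AKR1C genes are close paralogs, and the split of fragments among them is uncertain. In the unfolded protein response list, higher and lower calls numbered 13 and 4 of 24 in control, 9 and 8 of 24 in cisplatin, 13 and 5 of 24 in doxorubicin and 17 and 3 of 24 in tunicamycin (adjusted over the list alone, 14 and 4 in control, 13 and 6 in doxorubicin and 18 and 3 in tunicamycin). Calls were more frequent than among other genes in control, doxorubicin and tunicamycin (Fisher's exact test, adjusted p = 0.0351 in control, 0.0131 in doxorubicin and 0.00482 in tunicamycin). The medians were 0.21 in control, 0.02 in cisplatin, 0.23 in doxorubicin and 0.25 in tunicamycin, inside the middle 95% of matched lists in every table, while without genes of shifted segments the control median lay above it (0.26). SDF2L1 was higher in control (43.3 to 92.7), doxorubicin (17.5 to 34.4) and tunicamycin (455 to 735). PDIA4, a protein disulfide isomerase, was higher in control (70.2 to 137), cisplatin (46.8 to 70.5) and doxorubicin (99.7 to 204), and SEL1L, of ER-associated degradation, in tunicamycin (103 to 178). DNAJC3, on chromosome 13, was higher in tunicamycin at 53.5 to 127. Outside shifted segments, 14 of 20 tested members were higher and 2 lower in tunicamycin. PERK-ATF4 stress genes gave 6 and 6 of 18 in control, 7 and 8 of 19 in cisplatin, 3 and 6 of 16 in doxorubicin and 11 and 3 of 20 in tunicamycin (adjusted over the list alone, 12 and 3 in tunicamycin). They had more calls than other genes in cisplatin (Fisher's exact test, adjusted p = 0.0341). The cystine transporter SLC7A11 was higher in control (7.72 to 19.5), cisplatin (5.18 to 11.8) and tunicamycin (20.7 to 49.5). VLDLR was lower in the same tables (2.91 to 0.50, 3.67 to 0.608 and 10.4 to 4.73). The list of metallothioneins and drug transport gave 10 and 5 of 19 in control, 6 and 8 of 19 in cisplatin, 9 and 4 of 20 in doxorubicin and 13 and 5 of 20 in tunicamycin (the same counts adjusted over the list alone). ABCC3, a drug efflux pump (2.63 to 14.8 in control), and ALDH3A1 (0.703 to 3.96) were higher, and the copper transporter homolog SLC31A2 was lower (9.67 to 4.50). Its calls were more frequent than among other genes in control and tunicamycin (Fisher's exact test, adjusted p = 0.00887 in control and 0.00153 in tunicamycin). Its medians were 0.43 in control, -0.23 in cisplatin, 0.51 in doxorubicin and 0.54 in tunicamycin, above the matched lists in control, doxorubicin and tunicamycin. Without genes of shifted segments the control median lay inside the middle 95% (percentile 86.0), those of doxorubicin and tunicamycin stayed above it, and that of cisplatin lay below it (-0.25). Metallothionein genes are close paralogs.

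Genes of the extracellular matrix and of invasion, features of this mesenchymal line, differed in both directions. In the mesenchymal and invasion list, higher and lower calls numbered 16 and 6 of 27 in control, 11 and 11 of 27 in cisplatin, 13 and 7 of 26 in doxorubicin and 16 and 7 of 26 in tunicamycin (adjusted over the list alone, 11 and 12 in cisplatin and 16 and 8 in tunicamycin). They were more frequent than among other genes in each table (Fisher's exact test, adjusted p = 0.00108 in control, 0.00482 in cisplatin, 0.00622 in doxorubicin and 0.000512 in tunicamycin). SPARC was higher at 2.07 to 13.8 in control, 1.57 to 13.2 in cisplatin, 0.949 to 16.0 in doxorubicin and 1.01 to 8.28 in tunicamycin. TGFBI was higher in cisplatin (32.4 to 84.9) and doxorubicin (39.9 to 209.6), while MMP1 was lower in all 4. The median was 0.68 in control, -0.11 in cisplatin, 0.42 in doxorubicin and 0.50 in tunicamycin, above the matched lists in all but cisplatin. Collagens and matrix genes gave 11 and 4 of 18 in control, 6 and 8 of 17 in cisplatin, 10 and 5 of 18 in doxorubicin and 10 and 3 of 19 in tunicamycin (adjusted over the list alone, 7 and 8 in cisplatin and 11 and 5 in doxorubicin). Their medians were 0.78 in control, -0.36 in cisplatin, 0.53 in doxorubicin and 0.41 in tunicamycin. COL7A1, of anchoring fibrils, was 3.27 to 20.5 in control and 3.01 to 18.3 in tunicamycin, and COL6A2 was 5.25 to 37.7 and 7.90 to 46.3. COL4A1, of basement membranes, was 12 to 47.1 in control, 4.01 to 10.2 in cisplatin and 13.3 to 54.2 in doxorubicin and lies on chromosome 13 in a segment shifted upward. Under cisplatin COL8A1 was lower (9.54 to 2.94). The collagen median lay outside the middle 95% in each table, above it in control, doxorubicin and tunicamycin and below it in cisplatin. Without genes of shifted segments it was 0.44 in control, -0.63 in cisplatin and 0.39 in doxorubicin, outside the middle 95% on the same sides. In tunicamycin it was then -0.000782, inside the middle 95%. In control, cisplatin and doxorubicin calls were more frequent than among other genes (Fisher's exact test, adjusted p = 0.00622 in control, 0.0228 in cisplatin and 0.00622 in doxorubicin). Epithelial genes gave 8 and 4 of 16 in control, 6 and 6 of 18 in cisplatin, 8 and 4 of 16 in doxorubicin and 9 and 5 of 18 in tunicamycin (the same counts adjusted over the list alone). Desmoplakin, DSP (9.98 to 1.39), and EPCAM (5.09 to 1.29) were lower and occludin, OCLN (2.14 to 4.22), higher in control. The list had more calls than other genes in tunicamycin (Fisher's exact test, adjusted p = 0.0489). In this list the mean log2 ratio was negative in every table (-0.12 in control). The median was positive (0.28 in control) except in cisplatin (-0.06). Markers of other cell types were called as well. For fibroblast markers the numbers were 4 and 0 of 5 in control, 3 and 1 of 5 in cisplatin, 4 and 0 of 5 in doxorubicin and 4 and 1 of 5 in tunicamycin (adjusted over the list alone, 4 and 1 in control), and their median was above the matched lists in every table (1.31 in control, 0.73 in cisplatin, 1.87 in doxorubicin and 1.43 in tunicamycin). Only 5 of the 14 fibroblast markers were tested in each table, and the presence of fibroblasts in the cultures was not tested. TAGLN, an actin-binding protein (10.0 to 99.3), and PDGFRB (1.69 to 6.83) were higher in control. Luminal breast markers gave 6 and 3 of 9 in control, 5 and 3 of 10 in cisplatin, 2 and 2 of 7 in doxorubicin and 5 and 3 of 10 in tunicamycin (adjusted over the list alone, 2 and 3 in doxorubicin). GATA3 (0.742 to 3.82) and SPDEF (0.550 to 3.16) were higher and KRT19 (299 to 159) lower in control, where calls were more frequent than among other genes (Fisher's exact test, adjusted p = 0.00406). Leukocyte markers gave 3 and 0 of 4 in control, 3 and 1 of 5 in cisplatin, 4 and 0 of 5 in doxorubicin and 2 and 1 of 4 in tunicamycin (adjusted over the list alone, 4 and 1 in cisplatin). Their medians were 1.05 in control, 0.48 in cisplatin, 0.82 in doxorubicin and 0.21 in tunicamycin, above the matched lists in control and doxorubicin, and the list did not pass Fisher's exact test in any table. CSF1R (0.667 to 4.63) and CD68 (64.1 to 171) were higher in control, and LAPTM5 was lower in cisplatin (80.5 to 58.6) and tunicamycin (80.8 to 73.6).

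Immune genes were higher in KO cells for antigen presentation, and mixed otherwise. Antigen presentation genes gave higher and lower calls of 13 and 1 of 21 in control, 13 and 2 of 21 in cisplatin, 17 and 0 of 20 in doxorubicin and 14 and 1 of 21 in tunicamycin (adjusted over the list alone, 14 and 2 in cisplatin and 18 and 0 in doxorubicin). Their median log2 ratio of 0.80 in control, 0.33 in cisplatin, 0.80 in doxorubicin and 0.66 in tunicamycin lay above the matched lists in every table. More calls than among other genes were found in doxorubicin (Fisher's exact test, adjusted p = 0.00283). HLA-DRB1, a class II molecule, was 1.22 to 5.09 in control and 1.46 to 5.99 in tunicamycin, and the invariant chain CD74 was 70.5 to 198 and, in cisplatin, 96.0 to 197. HLA genes are polymorphic and alike in sequence, so fragments may be split among them. Inflammatory cytokines and NF-kB genes gave 8 and 3 of 20 in control, 9 and 8 of 22 in cisplatin, 5 and 6 of 22 in doxorubicin and 15 and 1 of 23 in tunicamycin (adjusted over the list alone, 9 and 3 in control and 6 and 7 in doxorubicin). Beside CSF3 and IL1B, the neutrophil chemokine CXCL2 was higher in cisplatin (0.525 to 2.52) and tunicamycin (1.23 to 7.64), and LIF in control (7.03 to 21.3). The medians were 0.53 in control, -0.03 in cisplatin, -0.10 in doxorubicin and 0.53 in tunicamycin, above the matched lists in control and tunicamycin. Calls were more frequent than among other genes in cisplatin (Fisher's exact test, adjusted p = 0.0314). Interferon-response genes gave 10 and 13 of 32 in control, 15 and 10 of 33 in cisplatin, 8 and 10 of 30 in doxorubicin and 11 and 12 of 33 in tunicamycin (adjusted over the list alone, 16 and 10 in cisplatin and 8 and 11 in doxorubicin). GBP1 was higher in each table (2.19 to 13.2 in control), and IFI27 was lower in cisplatin (5.64 to 1.51), doxorubicin (6.84 to 1.83) and tunicamycin (4.27 to 0.986). OAS2, on chromosome 12, was lower in control (4.28 to 1.31). Calls in this list were more frequent than among other genes in control and cisplatin (Fisher's exact test, adjusted p = 0.00864 in control and 0.0102 in cisplatin).

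Metabolic and signalling genes differed as well. Glycolysis genes gave higher and lower calls of 15 and 5 of 22 in control, 12 and 9 of 22 in cisplatin, 15 and 4 of 22 in doxorubicin and 15 and 3 of 22 in tunicamycin (adjusted over the list alone, 15 and 5 in doxorubicin). In each table calls were more frequent than among other genes (Fisher's exact test, adjusted p = 0.000161 in control, 0.000142 in cisplatin, 0.00108 in doxorubicin and 0.00887 in tunicamycin). The aldolase ALDOC was higher at 1.78 to 8.40 in control, 4.14 to 15.1 in cisplatin, 3.66 to 18.3 in doxorubicin and 2.42 to 8.61 in tunicamycin, whereas SLC2A1 was lower in cisplatin (347 to 174) and tunicamycin (727 to 421). Cholesterol and lipid synthesis genes gave 13 and 4 of 25 in control, 13 and 5 of 25 in cisplatin, 15 and 4 of 24 in doxorubicin and 16 and 4 of 25 in tunicamycin (adjusted over the list alone, 13 and 6 in cisplatin and 17 and 4 in tunicamycin). INSIG1 (14.2 to 39.1) and the desaturase SCD (21.7 to 50.9) were higher in control. The median of this list was 0.31 in control, 0.12 in cisplatin, 0.38 in doxorubicin and 0.25 in tunicamycin, above the matched lists in all but cisplatin, and that of glycolysis genes was above them in control (0.29). Calls in the cholesterol list were more frequent than among other genes in doxorubicin and tunicamycin (Fisher's exact test, adjusted p = 0.00482 in doxorubicin and 0.00887 in tunicamycin). Hypoxia and angiogenesis genes gave 8 and 5 of 19 in control, 8 and 8 of 21 in cisplatin, 6 and 5 of 16 in doxorubicin and 9 and 7 of 20 in tunicamycin (adjusted over the list alone, 9 and 8 in cisplatin and 9 and 8 in tunicamycin). ANGPTL4 (2.32 to 23.8) and the vasodilator peptide ADM (43.7 to 142) were higher and PDGFB (1.49 to 0.235) was lower in control. Calls in this list were more frequent in cisplatin and tunicamycin (Fisher's exact test, adjusted p = 0.0456 in cisplatin and 0.0215 in tunicamycin). Immediate early genes gave 7 and 8 of 26 in control, 4 and 18 of 28 in cisplatin, 10 and 4 of 24 in doxorubicin and 9 and 12 of 26 in tunicamycin (adjusted over the list alone, 7 and 9 in control and 11 and 4 in doxorubicin). The phosphatase DUSP1 was lower in control (115 to 63.4) and tunicamycin (81.7 to 28.6), KLF6 (27.1 to 12.1) and FOSL1 (185 to 107) in cisplatin, and JUN was higher in doxorubicin (2.31 to 5.21). Their median was -0.03 in control, -0.17 in cisplatin, 0.44 in doxorubicin and -0.27 in tunicamycin, below the matched lists in cisplatin and tunicamycin and above them in doxorubicin. Calls were more frequent in cisplatin and tunicamycin (Fisher's exact test, adjusted p = 0.00887 in cisplatin and 0.00622 in tunicamycin). Wnt, Notch and TGF-beta signalling gave 8 and 9 of 27 in control, 5 and 18 of 29 in cisplatin, 6 and 6 of 20 in doxorubicin and 4 and 10 of 28 in tunicamycin (adjusted over the list alone, 9 and 9 in control and 7 and 6 in doxorubicin). They had more calls than other genes in cisplatin (Fisher's exact test, adjusted p = 0.00622), and their median was below the matched lists in control (-0.28) and cisplatin (-0.32). ID2 was higher in control (4.41 to 26.1). Genes of the mitochondrial genome were called in every table, with lower and higher calls of 14 and 1 of 15 in control, 14 and 1 of 15 in cisplatin, 8 and 7 of 15 in doxorubicin and 15 and 0 of 15 in tunicamycin (the same counts adjusted over the list alone). Their medians were -0.24 in control, -0.49 in cisplatin, -0.07 in doxorubicin and -0.66 in tunicamycin, below the matched lists in all but control. None of these genes lies in a shifted segment, but against random lists without such genes the control median too lay below (percentile 2.00), as did that of G2/M genes in doxorubicin (2.35). MT-ND3 was 6118 to 2828 in control, 3147 to 1972 in cisplatin and 4457 to 2424 in tunicamycin, and in doxorubicin MT-CO1 was higher (11291 to 15041). For replication-dependent histones, whose mRNAs mostly lack poly(A) tails and so are poorly caught by mRNA libraries, lower and higher calls numbered 2 and 1 of 11 in control, 6 and 0 of 12 in cisplatin, 1 and 0 of 12 in doxorubicin and 5 and 0 of 13 in tunicamycin (adjusted over the list alone, 1 and 1 in control and 0 and 0 in doxorubicin). In doxorubicin histone calls were fewer than among other genes (Fisher's exact test, adjusted p = 0.0456). Their median was below the matched lists in cisplatin (-0.69).

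**Figure D3:**
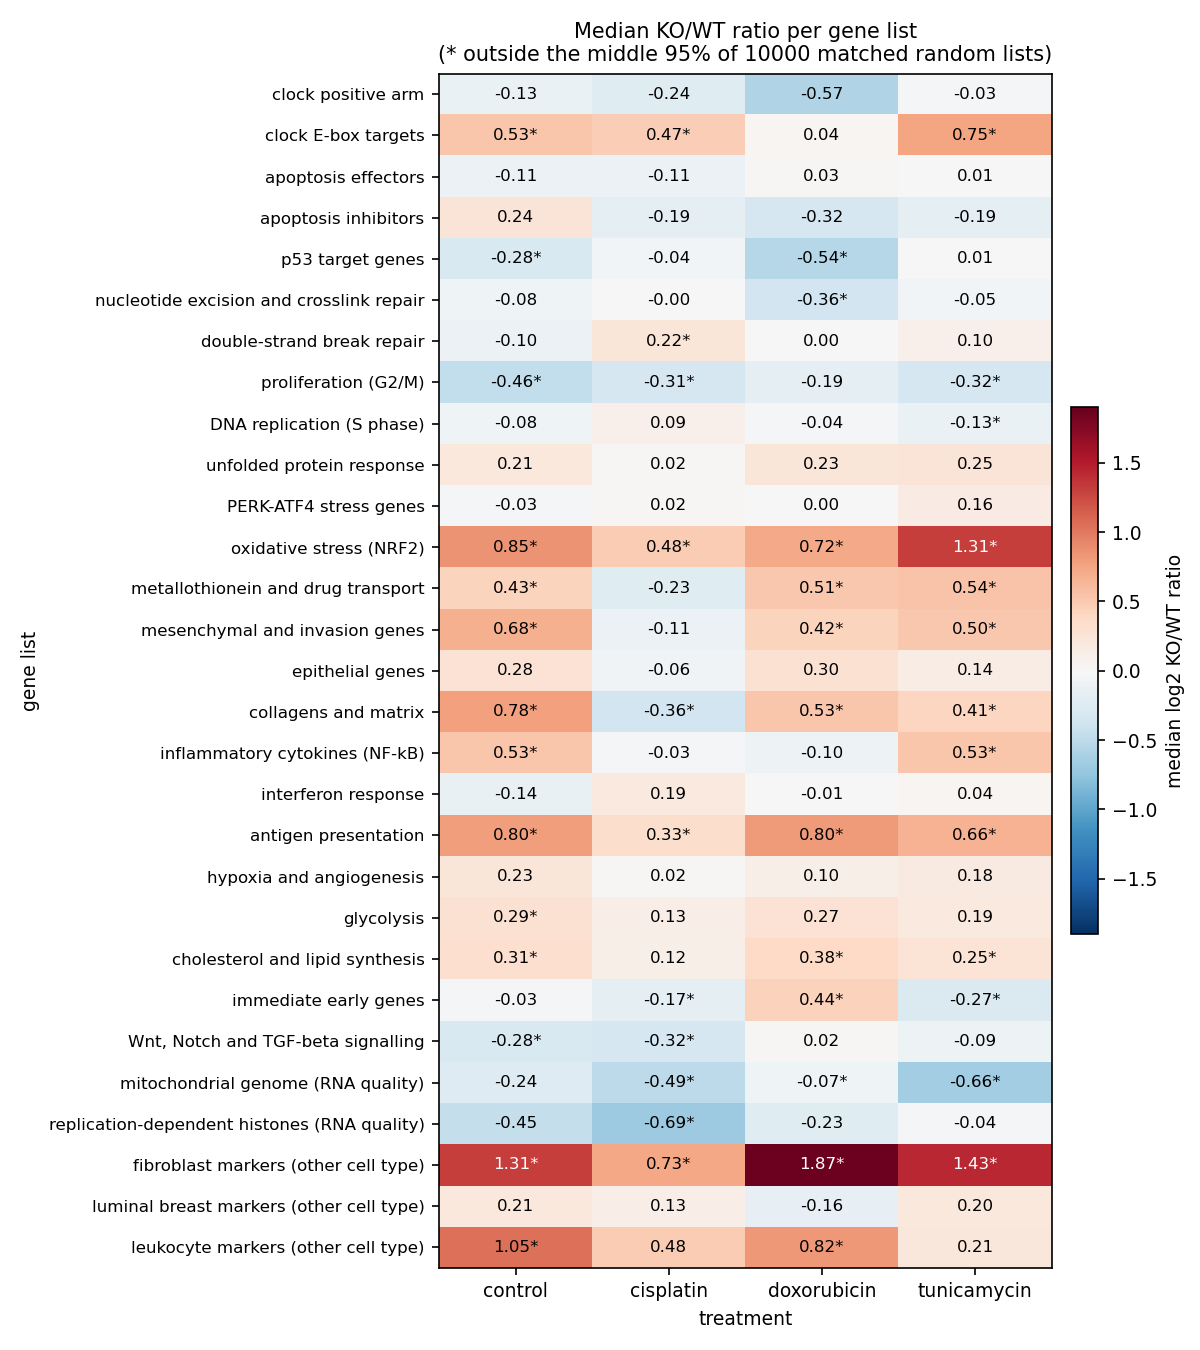
Each cell gives the median log2 KO/WT ratio of 1 of the 29 gene lists (vertical axis) in 1 of the 4 tables (horizontal axis), with red for higher and blue for lower in KO cells and a star outside the middle 95% of 10000 matched random lists. NRF2 targets were higher in every table (0.85 in control, 0.48 in cisplatin, 0.72 in doxorubicin and 1.31 in tunicamycin), and G2/M genes had negative medians (-0.46 in control, -0.31 in cisplatin, -0.19 in doxorubicin and -0.32 in tunicamycin).

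The response to each drug was compared between genotypes as the log2 ratio of treated over control FPKM, with 1 added, within WT and within KO cells. These values cross separately normalized tables and have no replicate spread, so none was tested. The median over all genes with a mean FPKM of at least 1 was 0.10 (WT) and 0.13 (KO) for cisplatin, -0.71 and -0.72 for doxorubicin and -0.08 and -0.07 for tunicamycin. List medians take all members with no minimum FPKM. Members near 0 FPKM have ratios near 0 on this scale and can draw a list median toward 0. The medians of all genes are therefore only a rough reference for the lists. Genes of FPKM 5 or more in 1 of the groups that differed at least 2-fold from control numbered 968 of 9351 in WT and 1153 of 9367 in KO cells for cisplatin, 4202 of 8939 and 4406 of 9008 for doxorubicin, and 565 of 9166 and 527 of 9150 for tunicamycin. Under tunicamycin the unfolded protein response list had a median of 1.79 in WT and 1.84 in KO cells, and PERK-ATF4 genes 1.33 in WT and 1.53 in KO cells. Doxorubicin gave medians of -3.94 in WT and -3.51 in KO cells for immediate early genes and -2.48 in WT and -2.46 in KO cells for G2/M genes, both far below the median of all genes. Glycolysis genes had 0.54 in WT and 0.73 in KO cells under doxorubicin, and mitochondrial genes 1.64 in WT and 1.93 in KO cells. Under cisplatin the p53 target list had 0.38 in WT and 0.48 in KO cells, G2/M genes -0.51 in WT and -0.33 in KO cells, and collagens and matrix genes -0.08 in WT and -0.50 in KO cells. The p53 target list had -1.05 in WT and -0.89 in KO cells under doxorubicin. Pearson's r of WT with KO responses across genes, which are not independent replicates, was 0.605 for cisplatin, 0.875 for doxorubicin and 0.545 for tunicamycin (Spearman's rho 0.656, 0.919 and 0.576).

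**Figure D4:**
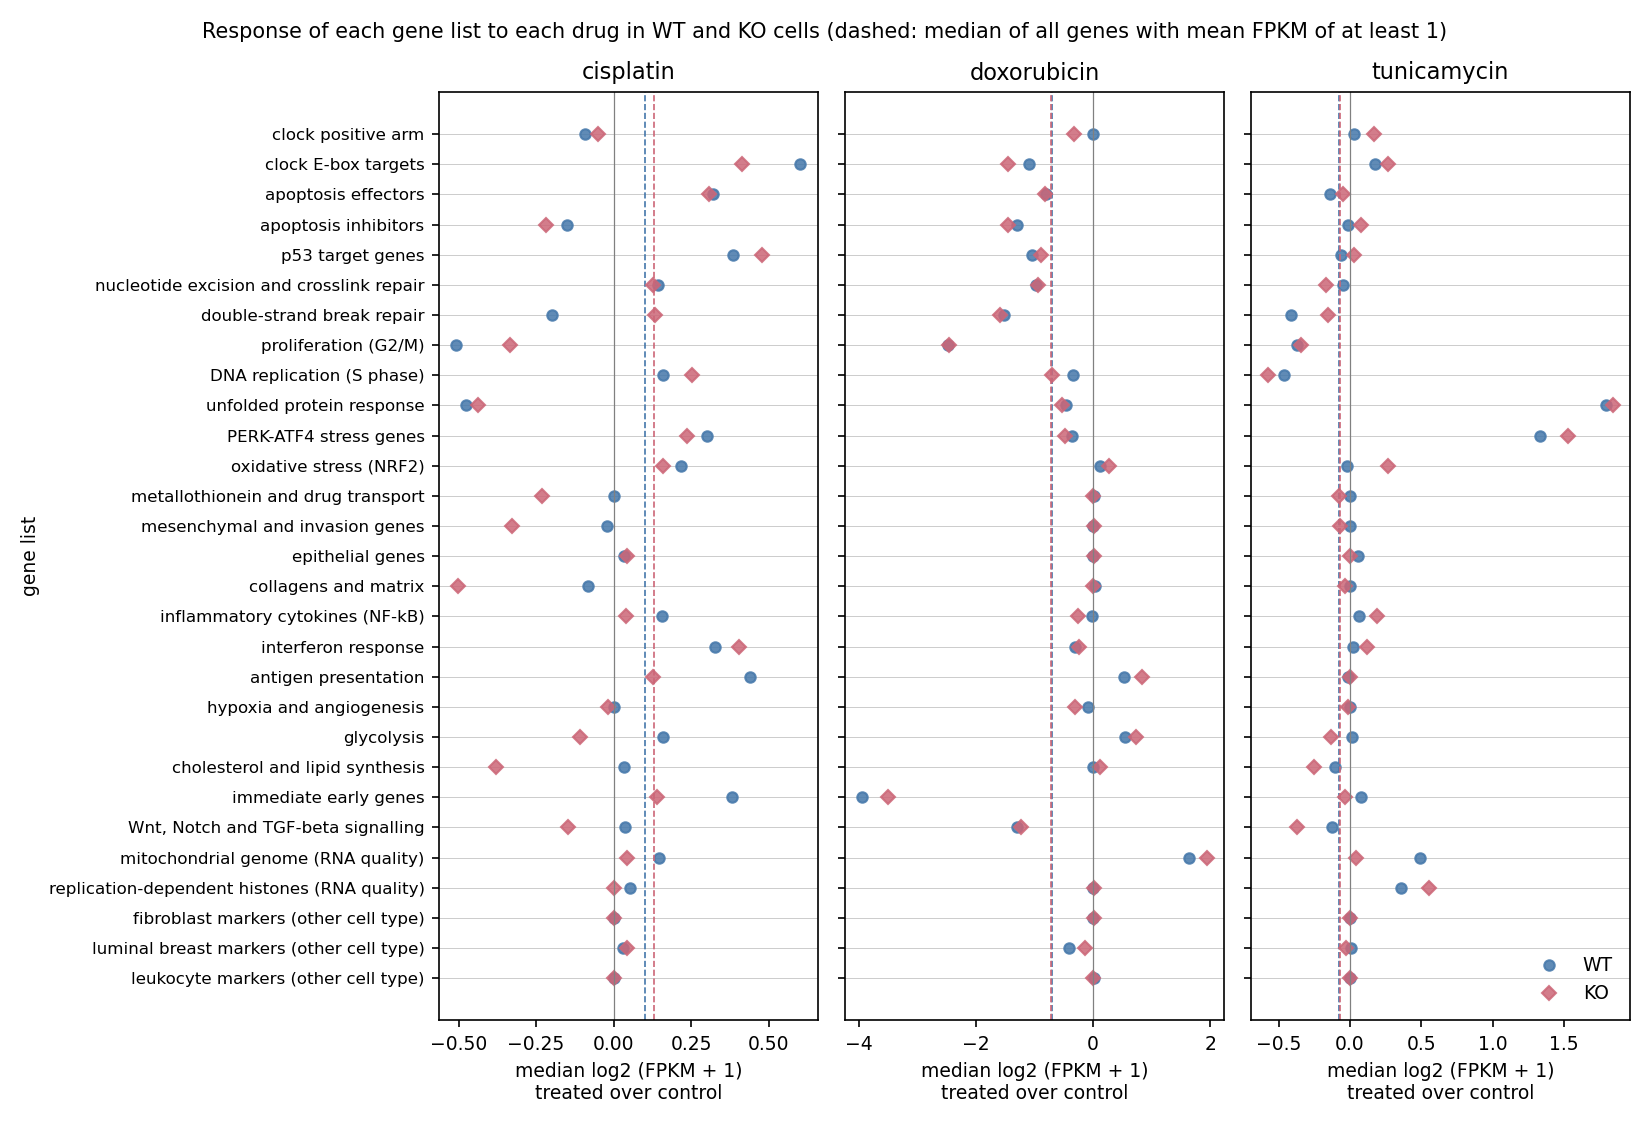
Points give the median log2 ratio of treated over control FPKM with 1 added (horizontal axis) for each gene list (vertical axis) in WT and KO cells under each drug, from separately normalized tables, and dashed lines give the median of all genes with a mean FPKM of at least 1. The lists take all their members with no minimum FPKM. Under tunicamycin the unfolded protein response list lay at 1.79 in WT and 1.84 in KO cells.

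Whether loss of BMAL1 altered the response to a drug was read from the difference between the log2 KO/WT ratio under drug and that in control. The deposited p-values did not follow the normal tail of the deposited statistic, so by the rule fixed before the data were examined this difference is a value with no test. Among genes of FPKM 5 or more in 1 group of each table, it was at least 1 in size for 490 of 8626 genes under cisplatin (148 up, 342 down), 344 of 6152 under doxorubicin (107 up, 237 down) and 222 of 8741 under tunicamycin (106 up, 116 down). These are 5.68%, 5.59% and 2.54% of genes. The 3 differences use the same control table, so its error enters each of them. In most of the largest differences the WT control group stood apart from the other 3, by a log2 gap wider than their range. This held for 20 of the 30 named differences, some of which repeat a gene across drugs, and for 292 of 1056 of at least 1 in size over the 3 drugs, a count made after the values were seen. An example is F8A2, which was 0.122 to 6.89 in control and 10.7 to 13.3 in cisplatin. Under cisplatin, doxorubicin and tunicamycin, WT control stood apart in 132, 61 and 99 of those at least 1 in size. The treated KO group did so in 88, 76 and 15. For the KO control group the counts were 87, 37 and 22, and for the treated WT group 16, 19 and 22. IL1B was 1.02 to 12.4 in control and 0.849 to 68.6 in tunicamycin, a difference of 2.73. TMEM135 was 8.43 to 5.14 in control and 3.31 to 9.95 in doxorubicin. By list, the median difference under cisplatin was -0.71 for collagens and matrix, -0.44 for cholesterol and lipid synthesis, -0.44 for antigen presentation, -0.41 for mesenchymal genes and -0.37 for glycolysis, each below the middle 95% of matched lists, and 0.22 for double-strand break repair, above it. Under doxorubicin it was 0.42 for immediate early genes and -0.46 for Wnt, Notch and TGF-beta signalling. Under tunicamycin it was 0.36 for NRF2 targets and -0.39 for the mitochondrial genome, also outside the middle 95%, and 0.07 for the unfolded protein response, inside it. Apoptosis effectors had medians of 0.00, 0.20 and 0.10 under cisplatin, doxorubicin and tunicamycin, all inside the middle 95%.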

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

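Of the tests in this part, that of neighbouring windows, that of the scale within each table, that of the share of ARNTL's change in WT cells, that of leukocyte markers, the count of differences in which 1 group stands apart and the z with the deposited statistic were chosen after the results were seen. Below, the difference is the log2 KO over WT ratio under a drug minus that in control, for the named genes whose difference passed both versions of a z at an adjusted p of 0.05, neither of which was the reported analysis. Levels in parentheses are FPKM from WT to KO. In 8 of these 10 differences (those of SNRPGP2, MINOS1-NBL1, POTEJ, RP11-386G11.10 and NSFP1), the WT control group stood apart from the other 3 groups, by a log2 gap wider than their range, so the differences of SNRPGP2 and POTEJ under several drugs repeat 1 control value each. SNRPGP2, a pseudogene, differed by 3.24 in cisplatin (109 to 12.4 in control and 13.9 to 15.1 in cisplatin). It differed by 2.76 in tunicamycin (12.3 to 9.54 in tunicamycin). The readthrough gene MINOS1-NBL1 differed by 2.80 in cisplatin (39.6 to 8.46 in control and 7.24 to 10.7 in cisplatin). POTEJ, of a family of close copies, differed by -4.98 in cisplatin (0.761 to 11.3 in control and 14.0 to 6.62 in cisplatin). Its difference was -4.40 in doxorubicin (22.7 to 15.9 in doxorubicin). In tunicamycin it was -4.83 (12.9 to 6.73 in tunicamycin). The antisense gene RP11-386G11.10 differed by 5.10 in doxorubicin (247 to 8.32 in control and 7.31 to 8.45 in doxorubicin). The pseudogene NSFP1 differed by -4.38 in doxorubicin (0.259 to 5.52 in control and 8.91 to 9.15 in doxorubicin). MIR100HG, a long noncoding RNA, differed by 3.76 in tunicamycin (181 to 47.1 in control and 23.7 to 83.5 in tunicamycin). SLC1A4, a neutral amino acid transporter, differed by 2.74 in tunicamycin (6.13 to 0.571 in control and 12.8 to 8.0 in tunicamycin).

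The same 979 genes were called higher and 942 lower in KO cells under all 4 treatments. A difference in scale left between the WT and KO values as deposited is argued against. The median log2 ratio was at most 0.0422 in size in any table, and both directions held many calls. The authors had normalized these values, so a difference removed at that step could not be seen here. A copy-number difference of chromosome segments is a candidate explanation for the calls inside shifted windows, where 12 pairs of neighbouring windows were shifted the same way, against at most 5 in 1000 random placements. Such windows held 18.5% of the recurring calls, between the 10% and 50% set as bounds before the result was seen, so a part played by copy number in the other calls cannot be told apart from effects of the knockout by expression alone. Loss of BMAL1, and a difference between clones in other respects, stay open as untested explanations.

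ARNTL was called lower in KO cells in control and doxorubicin and not in cisplatin and tunicamycin, and this contrast between tables was not itself tested. A difference in scale between tables cancels in the ratio of each table, so the change of ARNTL in WT cells from control to cisplatin (-1.56 log2 with 1 added, percentile 2.03 among 3720 genes of similar level) does not decide on the calls. A fall of ARNTL in treated WT cells is a candidate explanation in cisplatin, where 96.4% of the change of the log2 ratio from control lay in the WT value, although doxorubicin kept its call with WT cells at a similar FPKM (1.31 beside 1.26). In tunicamycin 37.6% lay in the WT value. As deposited, log2 FPKM changed from control by -0.80 in WT and by 1.33 in KO cells, so both entered the change. Whether the fall in WT cells accounts for the missing call was not decided. These shares cross separately normalized tables, and with no value per replicate a biological response of ARNTL to the drugs was not tested.

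Single genes known from leukocytes (LCP1, FERMT3 and CSF1R, picked after their values were seen) were higher in KO cells, while the fixed list of leukocyte markers did not pass Fisher's exact test (adjusted p = 0.466, 0.333, 0.289 and 0.511 in control, cisplatin, doxorubicin and tunicamycin) and had a median above matched lists in control (1.05) and doxorubicin (0.82). Cells of another type (leukocytes) in the KO cultures are argued against: of 15 leukocyte markers, 4 reached an FPKM of 1 in KO cells in every table (CORO1A, CD68, LAPTM5 and CSF1R), and 3 did so in WT cells. The pan-leukocyte gene PTPRC and 5 further markers were listed at 0 in KO cells in every table, while LCP1 was 28.6, 14.0, 42.3 and 29.5 in control, cisplatin, doxorubicin and tunicamycin. The most abundant of the markers, CD68 and LAPTM5, were at 171, 186, 434 and 173 and at 86.8, 58.6, 157 and 73.6 in KO cells, and at 64.1, 139.6, 235 and 147 and at 80.2, 80.5, 145 and 80.8 in WT cells. Expression by the cancer cells themselves, linked to the knockout or to the raised segment of chromosome 13 that holds LCP1, remains a hypothesis with no test of its own. The window that holds LCP1 had a median log2 ratio of 0.84 in control. LCP1 itself changed far more there, from 1.94 to 28.6.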

How the results depend on the processing

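The z with the deposited statistic and the removal of genes in shifted windows were chosen after seeing the data, and the other alternatives before. The counts at a log2 ratio of at least 1 were 1517 (genes called KO against WT, control), 1468 (genes called KO against WT, cisplatin), 1495 (genes called KO against WT, doxorubicin), 1415 (genes called KO against WT, tunicamycin). With the same minimum there were 285 calls shared between control and cisplatin, higher in KO and 363 calls shared between control and cisplatin, lower in KO, 308 calls shared between control and doxorubicin, higher in KO and 309 calls shared between control and doxorubicin, lower in KO, and 363 calls shared between control and tunicamycin, higher in KO and 407 calls shared between control and tunicamycin, lower in KO. Over all tables there were then 184 calls shared in all 4 treatments, higher in KO and 199 calls shared in all 4 treatments, lower in KO. These falls follow from the stricter threshold. The count of genes whose KO against WT ratio differs, cisplatin against control, was 1233 at a size of 1 with an FPKM of at least 1, 3036 by a z at an adjusted p of 0.05 with the standard error from the deposited p, and 2267 with that from the deposited statistic. For genes whose KO against WT ratio differs, doxorubicin against control, these counts were 1047, 1896 and 1494, and for genes whose KO against WT ratio differs, tunicamycin against control, 741, 1785 and 1446. The lower FPKM lets more genes in, and the z was run with no minimum size on all genes tested in both tables (12510, 10917 and 12613). Which of these raised its counts was not tested. Of 74 counts under alternatives, 53 stayed within 1.5 times the reported one, among them all at a q of 0.01. Also among them were 4 with the adjustment recomputed over the tested genes, which repeats the deposited q and so had to stay. Without genes in shifted windows, calls were 5030, 6291, 4780 and 6073 in the 4 tables, and 883 higher and 683 lower calls recurred in all. The median of collagens and matrix in tunicamycin then changed sign, to -0.000782, since members on chromosome 13 left the list. Of 580 list medians under alternatives, 561 stayed on their side of the bounds of the middle 95% of matched lists, 10 moved inside with the same sign, 8 moved outside and 1 that had lain outside changed sign. The percentiles of the 116 centred ones could not change, since centring moves a list and its random lists alike. Of the 561, 26 that lay inside as reported changed sign, 11 of them without genes in shifted windows and 11 when centred. Of 522 medians of drug response, 406 differed from the reported one after rounding to 2 decimals, among them all 174 that were centred. They also included 115 taken over members with an FPKM of at least 1 in 1 group. This count does not give the size of a change, and with 1 value per group no spread is at hand to judge it. Of 1136 q values of named genes under alternatives, 43 no longer passed, all at a q of 0.01 (12 in control, 10 in cisplatin, 14 in doxorubicin and 7 in tunicamycin), and 1 in doxorubicin left the genes tested at an FPKM of at least 1. No paired analysis was possible because the tables hold 1 value per group, so the replicate block could not be fitted, and leaving out each replicate could not be run for the same reason. Not run either were an adjusted p of 0.01 for the differences, which have no test as reported, and ratios centred on the median with p recomputed, since the deposited p-values do not follow the normal tail of the statistic. The precision behind single genes is limited by 2 samples per group and by a depth known only in relative terms.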

Other observations

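The share of genes shifted within windows was chosen after the result was seen, and it tests nothing. Further gene groups had a median difference between drug and control outside the middle 95% of matched lists, beyond which 5% of random lists lie by construction, and the 3 differences share the control table. Under cisplatin these were leukocyte markers (-0.79), hypoxia and angiogenesis (-0.41), inflammatory cytokines (-0.33), the unfolded protein response (-0.26) and immediate early genes (-0.25) on the low side. On the high side were interferon response (0.20) and S-phase replication (0.19). Under doxorubicin, fibroblast markers lay at 0.90, inflammatory cytokines at -0.41 and hypoxia genes at -0.35. Under tunicamycin, histones lay at 0.31, cholesterol and lipid synthesis at -0.31, mesenchymal genes at -0.13, S-phase replication at -0.12 and glycolysis at -0.08. Tunicamycin, the treatment meant as a comparison, had 6852 calls of KO against WT, and the median size of its difference from control was 0.259 log2, beside 0.320 for cisplatin and 0.294 for doxorubicin.

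KO over WT ratios under the drugs were correlated with each other across genes, which are not independent replicates. Pearson's r was 0.778 for cisplatin and doxorubicin, 0.806 for cisplatin and tunicamycin and 0.818 for doxorubicin and tunicamycin (Spearman's rho 0.634, 0.684 and 0.705). Each r exceeds those of control with the drugs, but the rho of cisplatin with doxorubicin is below that of control with tunicamycin (0.641). In the shifted windows of chromosome 13, 89.5% of 152 genes had a ratio above 0 in control. In those of chromosome 7 the share was 11.4% of 88 genes. CRY1 on chromosome 12 and LINC00452 on chromosome 13 ran against the direction of their windows.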
